A study of Mus musculus with 33 samples.

How the data were processed

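Gene expression was measured by 3' end RNA sequencing in macrophage subsets sorted by flow cytometry from the muscularis of the mouse colon. Per the labels' protocols, female mice of 8 to 9 weeks carried a green fluorescent reporter at the Cx3cr1 locus and a red one at the Ccr2 locus. They drank 3% dextran sodium sulfate (DSS), a polymer that injures the colonic epithelium and causes colitis, for 5 days and then water, or water throughout, and tissue was taken on day 7 or 8. Cells of 3 to 4 mice were combined into each replicate, and the 5 replicates came from 5 separate sorting experiments. Libraries were made from 1 ng of total RNA with an oligo(dT)-primed kit and 24 cycles of amplification, and were sequenced as paired reads of 50 bases, per the labels' protocols. Such libraries count fragments next to the polyadenylated end, so that gene length plays little part, and transcripts that share an end cannot be told apart.

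The deposited table holds whole-number counts of reads per gene for 56884 Ensembl gene identifiers in 33 libraries, not normalized by the authors. Per the submitters' processing notes, FastQC 0.11.9, Trimmomatic 0.36, STAR 2.7.5b and the genome build GRCm39 were used. The counting tool, the strand setting and the annotation release were not given in the sources used here. Whether PCR copies were merged by molecular identifiers was not given either, so that intervals and floors in the text cover counting error only. Symbols came from a table of GENCODE gene names of another mouse build, used for names alone, and no coordinates are given for that reason. It named 51948 of the identifiers, and the 4936 without a name held 2.39% of all counts. Genes whose reads overlap, such as Cfb with Gm20547 and Selenop with Ccdc152, are uncertain, since the counting could have assigned the same reads to either.

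Libraries were grouped by the sorted subset and the treatment in their labels, which gave 8 groups. Replicate numbers were those of the sorting experiments, except for the 2 water Ccr2+Ly6c+MHCII+ libraries. Each of these was combined from 3 sorts before sequencing, and both contain part of sort 5, so that they were not fully independent. The labels state that each replicate was a separate sorting experiment, and the shared numbers therefore pair libraries. Over 2629 genes with a mean log2 CPM (counts relative to library size) above 6, deviations from the group means correlated with a mean r of 0.0415 in 84 pairs of the same sort, from -0.0498 to 0.145, and of -0.0105 in 326 pairs of different sorts, from -0.133 to 0.118, across genes. Column names carry an index that splits the libraries into 8 with an index of 8 or lower and 25 above it, which was treated as a possible sequencing batch that the labels do not name. A term for it added to the groups called 40 genes, 19 higher and 21 lower in the 8 libraries, among them mt-Cytb, Actb and mt-Rnr1 of the 5 with the smallest p. The 8 hold at most 2 libraries of any group and so have no values of their own.

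Differences were tested with edgeR 4.0.16 in R 4.3.3. One quasi-likelihood model with robust estimation and the 8 groups was fitted to all 33 libraries after TMM normalization, and each comparison was a contrast of that model. Genes had to pass filterByExpr by group with its minimum count of 10, which left 15128 genes. Genes with a Benjamini-Hochberg adjusted p below 0.05 are described as called, higher or lower. Mean levels are TMM-normalized CPM with the SD over libraries, and fold changes are on the log2 scale with their standard error (SE). Of the tested values, 42.0% were 0. The common dispersion was 3.29. At median prior degrees of freedom of 5916, most genes' own spread was almost wholly replaced by the trend over abundance. Most genes steadier or noisier than others of their level were thus treated alike. Where a group had no count of a gene, the fitted fold was replaced by one against 3 counts over the whole group. Such "at least" folds leave out spread between libraries.

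The genes named were set by a rule written before the data were examined. It took the genes of the sorting gates in every group. For the 3 DSS effects and for Ccr2+ against MHCII+ it took the 10 genes with the largest fold in each direction among called genes with a mean CPM of at least 20 in the higher group, no overlap between the libraries of the groups, and no predicted or clone name. Other comparisons took 5 in each direction, without the overlap condition for the difference between DSS effects. It also took up to 2 called members in each direction from each of 26 gene lists, or, from lists with none, the 2 with the smallest adjusted p. These lists, of macrophage programmes and of markers of other cell types, were fixed at the same time with 402 genes, of which 342 could be tested. Genes outside the rule are identified in the text.

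Each list with at least 5 tested genes, 25 in all, was tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the lists of each comparison. The list of mast cell and eosinophil markers had 2 tested members and was left out. Camera ran on voom's log2 CPM without weights and with a variance trend. With voom's own smoothing span of 0.5 the trend fell to -0.499 and weights reached 3.33e+15, so that the weighted tests run first were not valid. Unweighted values were chosen after those first results had been seen and before their own were. The weighted version with a span of 0.1, whose weights ranged from 0.0841 to 27.7, became an alternative.

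Alternatives planned before the data were examined were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma-voom with sample quality weights (run with the span of 0.1), a fit of the compared groups alone, a block for the sorting experiment, camera with an estimated correlation, and leaving out each library in turn. Libraries under 1000000 counts were also to be left out, but none was that shallow. Added after seeing the data were a term for the column index, a fit of the 25 libraries with an index above 8, a fit without the libraries of sort 5, camera in these 3 fits, and camera with each library left out. The closing section gives their effects.

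The method was tested on simulated counts, drawn for the real genes with 1 mean per gene over all libraries, the fitted dispersions and the real library sizes. In each of 3 comparisons 200 genes with a mean CPM of at least 20 were changed, 50 at each of 4 fold sizes. For DSS against water in MHCII+ it called 0, 8, 24 and 48% of the genes changed 2, 4, 8 and 16-fold, with 1 false call among 15128 genes. The values were 0, 6, 24 and 42% in Ccr2+MHCII+ and 0, 0, 16 and 30% in Ccr2+Ly6c+MHCII+, with 0 false calls in each. A set of 20 genes raised 2-fold was called in MHCII+ (adjusted p = 4.58e-04) but not in Ccr2+MHCII+ (0.319) or Ccr2+Ly6c+MHCII+ (0.203). Of 25 unchanged sets in each comparison, 1 was called in MHCII+ and 0 in the others. Changes of 4-fold or less in such genes were therefore seldom detectable, and genes without a call cannot be taken as unchanged. Estimated folds of the simulated genes that were called ran above the true ones: in MHCII+ the 4 called genes with a true fold of 4 had a median estimate of 10.1, and the 24 with a true fold of 16 one of 20.5.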

Results

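RNA of macrophage subsets sorted from the muscularis of the colon was sequenced in 33 libraries of mice given DSS or water. The 4 DSS groups were Ccr2+ (5 libraries), Ccr2+Ly6c+MHCII+ (5), Ccr2+MHCII+ (5) and MHCII+ (4). The 4 water groups were Ccr2+Ly6c+MHCII+ (2), Ccr2+MHCII+ (4), MHCII+ (5) and DN (3), the last negative for Ly6c and MHCII by the labels. Total counts ranged from 3078970 to 6373040, and 7456 to 10851 genes had a count in a library. Spearman correlations across genes between libraries of a group lay between 0.595 and 0.7504 in 56 pairs. Mitochondrial transcripts made up 10.1% ± 1.45 of counts in DSS MHCII+ and 9.22% ± 1.31 in water MHCII+, and between 4.92 and 7.94% on average in the 6 other groups.

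Levels below are mean CPM ± SD in the order of the groups compared, and log2 fold changes are given ± SE with edgeR's adjusted p. Genes described as higher or lower were called. Where a call was lost without 1 library, among the 25 libraries with a column index above 8, or with the sorting experiment as a block, the adjusted p of that fit follows. Lists whose call was lost in 2 or more of the fits without 1 library are counted with each comparison, and of these the markers of other cells are described there.

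Transcripts of the sorting markers were examined first, as a check of the labels. Groups were sorted on these markers, so that list calls along a gate were partly set by the sort. The MHC class II list holds H2-Ab1, H2-Aa, H2-Eb1 and Cd74, and the classical monocyte list holds Ccr2 and Ly6c2. Ccr2 (ENSMUSG00000049103), the chemokine receptor of classical monocytes, averaged 544 ± 143 CPM in DSS Ccr2+, 575 ± 139 in DSS Ccr2+Ly6c+MHCII+ and 337 ± 66.8 in DSS Ccr2+MHCII+. In DSS MHCII+ it averaged 51.5 ± 27.8. The water groups had 609 ± 119 in Ccr2+Ly6c+MHCII+, 366 ± 151 in Ccr2+MHCII+, 41.8 ± 12.9 in MHCII+ and 21.6 ± 19.1 in DN. Ly6c2 reached 429 ± 202 CPM in DSS Ccr2+, 208 ± 122 in DSS Ccr2+Ly6c+MHCII+ and 465 ± 359 in water Ccr2+Ly6c+MHCII+. Its mean in the other groups was at most 8.56 ± 16.0. The MHC class II gene H2-Ab1 (ENSMUSG00000073421) averaged 204 ± 108 CPM in DSS Ccr2+ and 109.8 ± 22.3 in DN. In the 6 groups sorted as MHCII+ its means lay between 7459 ± 565 and 14283 ± 889. Cx3cr1, the fractalkine receptor and the locus of the green reporter, averaged 691 ± 152 CPM in DSS MHCII+ and 642 ± 109 in water MHCII+.

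**Figure D1:**
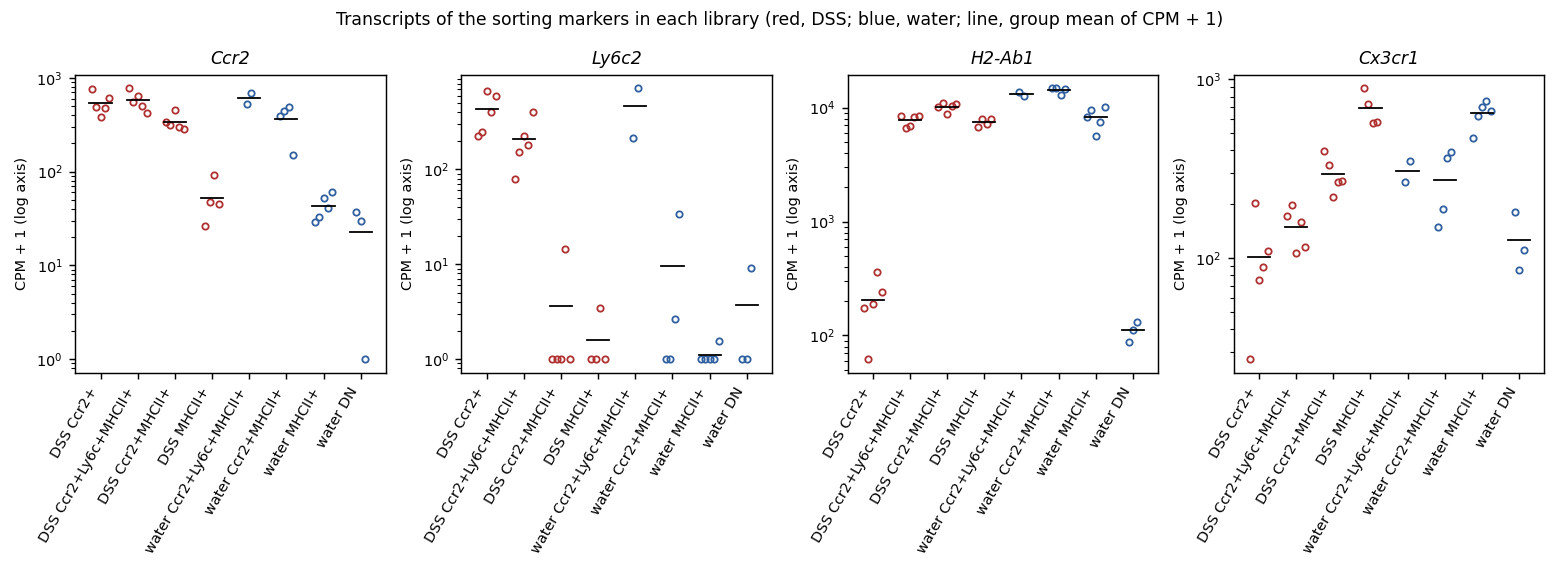
CPM + 1 on a log axis for Ccr2, Ly6c2, H2-Ab1 and Cx3cr1, with 1 point per library (red, DSS; blue, water) and a line at each group's mean of CPM + 1. Libraries of the DSS Ccr2+ and water DN groups lie far below all others for H2-Ab1.

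The DSS effect in MHCII+ cells (4 DSS against 5 water libraries) asked how this subset differs in colitis. Il1b, which encodes the inflammatory cytokine interleukin 1 beta, rose from 355 ± 73.8 to 1004 ± 94.9 CPM (log2 fold change 1.499 ± 0.21, adjusted p = 1.68e-06). Il1r2 (49.1 ± 66.8 against 0.101 ± 0.226 CPM, adjusted p = 4.13e-04), the decoy receptor of interleukin 1, was higher. Fpr1 (38.5 ± 32.4 against 0 CPM, adjusted p = 0.00972), a receptor for formylated bacterial peptides, had no count in water. Emb (log2 fold change 2.71 ± 0.42, adjusted p = 4.65e-07, 0.246 above index 8) was higher. Itgam (log2 fold change 0.98 ± 0.22, adjusted p = 0.00654, 0.419 without DSS MHCII+ replicate 2 and 0.0599 without water MHCII+ replicate 4), the alpha chain of the integrin CD11b, was higher too. Adgre5 (68.3 ± 32.8 against 278 ± 101 CPM, log2 fold change -2.03 ± 0.35, adjusted p = 8.69e-06) fell. Ahnak (347 ± 86.3 against 999.7 ± 291 CPM, log2 fold change -1.53 ± 0.23, adjusted p = 7.34e-08) fell, as did Anxa2 (121 ± 99.8 against 400.1 ± 116 CPM). S100a10 (158 ± 102 against 451 ± 72.0 CPM, adjusted p = 3.73e-05, 0.0516 above index 8), the binding partner of annexin A2, was lower. So were the small calcium-binding protein gene S100a6 (406 ± 151 against 1002 ± 244 CPM) and the galectin gene Lgals1 (522 ± 163 against 1324 ± 340.00 CPM). Nrg1, a growth factor for glia and neurons, had 13.5 ± 15.9 against 0 CPM (adjusted p = 0.0311). Its adjusted p was 0.0510 to 0.0787 without DSS MHCII+ replicate 2 or 4 or any 1 of the 5 water libraries. It was 0.127 above index 8.

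Inflammatory cytokine and NF-kB response genes were higher (camera adjusted p = 1.44e-04), with 1 of 23 higher over all genes and 4 adjusted over the list alone. Dissociation and immediate-early genes were lower (camera adjusted p = 3.12e-13), with 1 of 18 lower over all genes and 10 adjusted over the list alone. Genes of this list respond within minutes to handling and other stimuli. Resident muscularis macrophage genes were lower (camera adjusted p = 2.36e-05, adjusted p = 0.166 with an estimated correlation), with 0 of 22 lower over all genes and 2 adjusted over the list alone. Alternative activation genes were lower (camera adjusted p = 0.00596, adjusted p = 0.104 with an estimated correlation, 0.271 without DSS MHCII+ replicate 2). They summed to 6518 ± 2212 against 15157 ± 2332 CPM. Markers of other cells moved with these groups: B cell and plasma cell markers were higher (camera adjusted p = 2.06e-04, 0.789 above index 8), at summed 722 ± 310.3 against 479 ± 115 CPM. Their test pointed the other way above index 8. Dendritic cell markers were called higher (camera adjusted p = 0.0139, adjusted p = 0.104 with an estimated correlation, lost at up to 0.0971 without DSS MHCII+ replicate 2 or 5 or water MHCII+ replicate 4), at summed 991 ± 183 against 639.8 ± 129 CPM. Over all genes 33 genes were called, 20 higher and 13 lower. Among libraries with a column index above 8 the number was 53. 11 of the 19 called genes named by the rule and 4 of the 6 called lists kept the call whichever library was left out.

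In Ccr2+MHCII+ cells (5 DSS against 4 water libraries), Il1b (2846 ± 512 against 638 ± 191 CPM, log2 fold change 2.16 ± 0.23, adjusted p = 1.64e-10) was higher under DSS. Tgfbi (1073 ± 391 against 339.7 ± 211 CPM, log2 fold change 1.66 ± 0.30, adjusted p = 8.79e-04), a matrix protein gene, was higher. Cfb (34.1 ± 26.1 against 0 CPM, at least 169-fold, adjusted p = 2.01e-04), which encodes complement factor B but overlaps Gm20547, had no count in water. Zcchc9 (log2 fold change 4.64 ± 0.94) and Dok3 (log2 fold change 2.96 ± 0.60), an adaptor gene of myeloid signalling, were higher. Vcan (42.3 ± 29.2 against 0 CPM, at least 209-fold, adjusted p = 0.0211, 0.0779 with the block), the gene of the proteoglycan versican, had no count in water. The chemokine gene Cxcl16 (443 ± 76.8 against 132 ± 60.6 CPM, adjusted p = 0.00332, 0.0752 without water Ccr2+MHCII+ replicate 5) was higher. Col3a1 (45.0 ± 61.8 against 0.445 ± 0.889 CPM, adjusted p = 0.00700, 0.0830 without DSS Ccr2+MHCII+ replicate 4), a collagen gene of fibroblasts, was higher. Txnip (151 ± 65.3 against 466 ± 129 CPM, log2 fold change -1.63 ± 0.34, adjusted p = 0.00171), a regulator of thioredoxin and glucose uptake, fell. Anxa2 (455 ± 65.5 against 1296 ± 222 CPM) and Ahnak (903 ± 203 against 1846 ± 294 CPM) fell. The signalling inhibitor Socs3 (log2 fold change -1.05 ± 0.21) and the actin-binding Tagln2 (log2 fold change -1.10 ± 0.20) fell as well. S100a6 (2284 ± 431 against 4214 ± 627 CPM) was lower. S100a10 (595 ± 92.6 against 1374 ± 425 CPM, adjusted p = 0.00320, 0.0905 without water Ccr2+MHCII+ replicate 3) was lower. Jun (915 ± 145 against 1617 ± 291 CPM, adjusted p = 0.00700, 0.0856 without water Ccr2+MHCII+ replicate 2), an immediate-early transcription factor gene, was lower.

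Inflammatory cytokine and NF-kB response genes were higher (camera adjusted p = 1.76e-05), with 2 of 23 higher over all genes and 5 adjusted over the list alone. MHC class II antigen presentation genes were not called (camera adjusted p = 0.0544), but were with the sorting experiment as a block (adjusted p = 0.0358). Among markers of other cells, fibroblast markers were called higher (camera adjusted p = 0.0462, adjusted p = 0.463 with an estimated correlation, 0.105 above index 8, 0.213 without sort 5, lost at up to 0.392 without DSS Ccr2+MHCII+ replicate 3, 4 or 5 or water Ccr2+MHCII+ replicate 2 or 5), at summed 761 ± 153 against 506 ± 139 CPM. Over all genes 52 genes were called, 39 higher and 13 lower. 13 of the 28 called genes named by the rule and 1 of the 3 called lists kept the call whichever library was left out.

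In Ccr2+Ly6c+MHCII+ cells (5 DSS libraries against 2 water pools), Il1b (4655 ± 1068 against 1446 ± 60.04 CPM, log2 fold change 1.69 ± 0.29, adjusted p = 4.48e-04) was higher under DSS. Lmnb1 (1095 ± 370.2 against 216 ± 30.2 CPM, log2 fold change 2.34 ± 0.41, adjusted p = 4.19e-05, 0.0659 without water Ccr2+Ly6c+MHCII+ replicate 1), the gene of lamin B1, was higher. Pim1 (2637 ± 522 against 969 ± 67.6 CPM, adjusted p = 6.53e-04, 0.0640 without water Ccr2+Ly6c+MHCII+ replicate 1), which encodes a serine kinase, was higher too. Ahnak (709 ± 216 against 3097 ± 1418 CPM, log2 fold change -2.13 ± 0.25, adjusted p = 1.35e-12) was lower. S100a10 (460.5 ± 34.0 against 1522 ± 65.3 CPM, log2 fold change -1.72 ± 0.31, adjusted p = 7.77e-05) was lower. Cd24a (0 against 83.1 ± 28.0 CPM, at least 616-fold, adjusted p = 0.00458), a surface glycoprotein gene, had no count under DSS. The water pools held more genes, 10779.5 ± 101 detected against 8870.2 ± 806 under DSS, with 32.3% against 43.7% of tested values at 0, and 6 of the 23 lower genes had no count under DSS. The calls of Il1b, Ahnak, S100a10 and Cd24a were kept in every fit without 1 library. Lgals3 (739.98 ± 142 against 1946 ± 137 CPM, adjusted p = 0.00140, 0.196 without water Ccr2+Ly6c+MHCII+ replicate 1 and 0.0717 without water Ccr2+Ly6c+MHCII+ replicate 2), the gene of galectin 3, was lower. S100a6 (2191 ± 509 against 4472 ± 0.711 CPM, adjusted p = 0.00133, 0.0732 without water Ccr2+Ly6c+MHCII+ replicate 1 and 0.0931 without water Ccr2+Ly6c+MHCII+ replicate 2) was lower. Crip1 (2331 ± 716 against 9366 ± 2715 CPM, adjusted p = 0.00458, 0.422 without water Ccr2+Ly6c+MHCII+ replicate 2) and Lmna (154 ± 121 against 675 ± 284 CPM, adjusted p = 0.00446, 0.477 without water Ccr2+Ly6c+MHCII+ replicate 1), the gene of lamins A and C, were lower. Retnla, an alternative activation gene, averaged 1479.9 ± 768 against 23580.5 ± 1313 CPM and was not called (adjusted p = 0.165).

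Epithelial markers were lower under DSS in this subset (camera adjusted p = 1.76e-09, adjusted p = 0.230 with an estimated correlation), with 0 of 14 lower over all genes and 0 adjusted over the list alone. Both water pools contain cells of sort 5, whose libraries held high levels of these markers. Over all genes 29 genes were called, 6 higher and 23 lower. The number was 12 without water Ccr2+Ly6c+MHCII+ replicate 1, 16 without replicate 2 and 47 without DSS Ccr2+Ly6c+MHCII+ replicate 2. It was 64 among libraries with an index above 8 and 44 without sort 5. 4 of the 18 called genes named by the rule and 1 of the 6 called lists kept the call whichever library was left out.

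Across the 3 DSS effects, which share sorting experiments but no library, 6 genes were lower in every subset and 2 were higher. This set was chosen after its values were seen. In the order MHCII+, Ccr2+MHCII+ and Ccr2+Ly6c+MHCII+, log2 fold changes were given by Ahnak (-1.53 ± 0.23, -1.03 ± 0.22 and -2.13 ± 0.25), Anxa2 (-1.73 ± 0.28, -1.51 ± 0.27 and -1.43 ± 0.32) and S100a10 (-1.52 ± 0.27, -1.21 ± 0.26 and -1.72 ± 0.31). In the same order the other lower genes were S100a6 (-1.30 ± 0.18, -0.88 ± 0.17 and -1.03 ± 0.21), Lgals1 (-1.34 ± 0.22, -0.87 ± 0.21 and -1.03 ± 0.26) and Tagln2 (-0.91 ± 0.21, -1.10 ± 0.20 and -1.19 ± 0.24). Il1b was higher in all 3, and so was Ms4a6d (1.43 ± 0.32, 1.65 ± 0.33 and 1.81 ± 0.44). Lower calls shared by MHCII+ and Ccr2+MHCII+ numbered 6, against 0.0112 expected of independent lists. Ccr2+Ly6c+MHCII+ shared 7 with MHCII+ (0.0198 expected) and 8 with Ccr2+MHCII+ (0.0198 expected). These expected values leave out the shared sorting experiments. Of the 18 calls of the lower genes, 17 were kept among libraries with an index above 8. Ahnak and Il1b kept all 3 calls whichever library was left out, but without the libraries of sort 5 the calls of Ahnak (0.0587) and Lgals1 (0.115) in Ccr2+MHCII+ and of Lgals1 (0.159) in Ccr2+Ly6c+MHCII+ were lost. In MHCII+, the adjusted p of Tagln2 was 0.0503 to 0.138 without DSS replicate 2, 3 or 5 or water replicate 2 or 4, and that of Ms4a6d 0.0677 and 0.0753 without water replicate 4 and 5. Ms4a6d had 0.319 there without sort 5. In Ccr2+MHCII+, Lgals1 had 0.0787 to 0.273 without DSS replicate 2, 3 or 5 or water replicate 2 or 3, and S100a10 0.0905 without water replicate 3. In Ccr2+Ly6c+MHCII+ without water pool 1, values were 0.348 for Anxa2, 0.319 for Lgals1, 0.0732 for S100a6 and 0.290 for Ms4a6d. Without pool 2 they were 0.178, 0.827, 0.0931 and 0.827, and 0.299 for Tagln2. Lgals1 had 0.133 and 0.222 without DSS replicate 3 and 5, and Ms4a6d 0.0839 without DSS replicate 1.

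**Figure D2:**
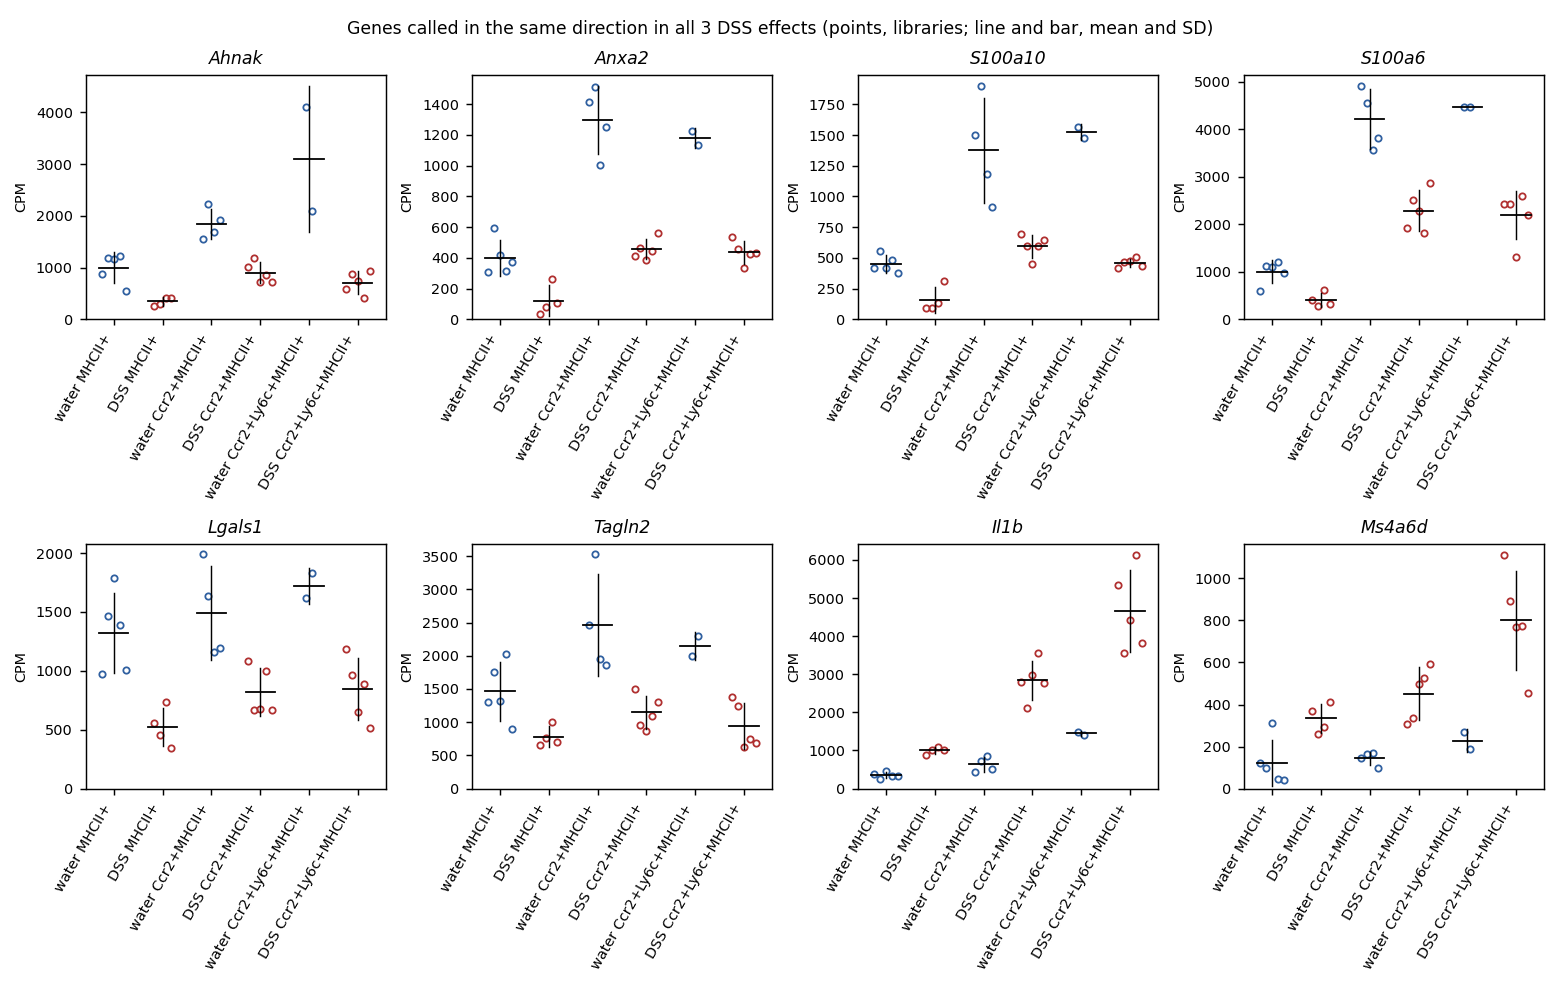
CPM of the 6 genes called lower and the 2 called higher under DSS in MHCII+, Ccr2+MHCII+ and Ccr2+Ly6c+MHCII+ cells, with 1 point per library (red, DSS; blue, water) and each group's mean and SD. Il1b averaged 1004 under DSS against 355 CPM in MHCII+, and Ahnak 347 against 999.7.

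Ccr2+ cells were compared with MHCII+ cells under DSS (5 against 4 libraries). Ccr2+ cells had higher S100a4 (1182 ± 448 against 56.5 ± 46.0 CPM, log2 fold change 4.39 ± 0.49, adjusted p = 3.52e-07). S100a6 (3110.01 ± 761 against 406 ± 151 CPM, log2 fold change 2.94 ± 0.19, adjusted p = 1.38e-42) was higher. Vcan (558 ± 201 against 0.455 ± 0.909 CPM, log2 fold change 10.19 ± 1.75, adjusted p = 0.00147) and Il1b (4188 ± 813 against 1004 ± 94.9 CPM) were higher. Osm (564 ± 142 against 139.8 ± 20.0 CPM, log2 fold change 2.01 ± 0.38, adjusted p = 2.73e-05), the gene of the cytokine oncostatin M, was higher. The coagulation factor gene F10 (267 ± 59.7 against 0 CPM, at least 1217-fold, adjusted p = 8.92e-04) and the proteinase 3 gene Prtn3 (133 ± 83.2 against 0 CPM) had no count in MHCII+ cells. Arg1 (225 ± 166 against 0 CPM, adjusted p = 0.00498, 0.0512 without DSS MHCII+ replicate 3), the arginase gene of alternative activation, had none either.

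MHCII+ cells had higher MHC class II genes, with H2-Ab1 (log2 fold change -5.19 ± 0.30, adjusted p = 1.63e-12) and H2-Eb1 (log2 fold change -6.75 ± 0.43). The complement gene C1qa (959 ± 307 against 5910.02 ± 587 CPM, log2 fold change -2.62 ± 0.21, adjusted p = 8.50e-13) was lower in Ccr2+ cells. So were C1qb (727 ± 308 against 3304 ± 377 CPM) and the mannose receptor gene Mrc1 (175 ± 98.8 against 747 ± 197 CPM). The chemokine genes Ccl4 (65.4 ± 63.4 against 973 ± 95.9 CPM) and Ccl3 (87.1 ± 28.9 against 838 ± 168 CPM) were lower in Ccr2+ cells. The immediate-early genes Jun (542 ± 126 against 2487 ± 555 CPM) and Egr1 (483 ± 219 against 1653 ± 352 CPM) were lower. Immunoglobulin transcripts were found in MHCII+ libraries, with Igkc (0 against 246 ± 139.9 CPM, at least 1584-fold, adjusted p = 1.77e-06) and Ighm (16.98 ± 15.1 against 297 ± 179.5 CPM).

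Classical monocyte genes were higher (camera adjusted p = 1.30e-35), with 9 of 16 higher over all genes and 14 adjusted over the list alone. Glycolysis and hypoxia genes were higher (camera adjusted p = 9.57e-07), with 2 of 16 higher over all genes and 2 adjusted over the list alone. Matrix and protease genes were called higher (camera adjusted p = 0.00207) with a positive median and a negative mean log2 fold change. Of 18 genes, 5 were higher and 3 lower over all genes, and 7 and 4 adjusted over the list alone. Resident muscularis macrophage genes were lower (camera adjusted p = 6.01e-29), with 8 of 22 lower over all genes and 15 adjusted over the list alone. MHC class II antigen presentation genes were lower (camera adjusted p = 6.47e-32), with 6 of 10 lower over all genes and 9 adjusted over the list alone. Alternative activation genes were lower (camera adjusted p = 1.76e-04), with 6 of 15 lower over all genes and 9 adjusted over the list alone. Arg1 and Chil3 of that programme were higher. Chemokine and monocyte-recruitment genes were lower (camera adjusted p = 5.53e-04), with 7 of 22 lower over all genes and 9 adjusted over the list alone. Efferocytosis and scavenger receptors were lower (camera adjusted p = 0.00147), with 3 of 17 lower over all genes and 6 adjusted over the list alone. Cell cycle genes were lower (camera adjusted p = 0.00122), with 1 of 19 lower over all genes and 9 adjusted over the list alone. Dissociation and immediate-early genes were lower (camera adjusted p = 1.04e-04), with 6 of 18 lower over all genes and 8 adjusted over the list alone. RNA composition moved with these groups: mitochondrial transcripts made up 6.36% ± 1.10 of counts in Ccr2+ against 10.1% ± 1.45 in MHCII+, and ribosomal protein genes 3.92% ± 0.832 against 2.67% ± 0.862.

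Markers of other cells moved between these groups too. Neutrophil markers were higher in Ccr2+ cells (camera adjusted p = 6.87e-06), at summed 872 ± 442 against 56.6 ± 22.5 CPM. B cell and plasma cell markers were lower (camera adjusted p = 7.22e-10), with 3 of 9 lower over all genes and 7 adjusted over the list alone. Smooth muscle markers were lower (camera adjusted p = 6.68e-04), with 2 of 12 lower over all genes and 3 adjusted over the list alone. Enteric neuron markers were called lower (camera adjusted p = 0.0116, adjusted p = 0.112 with an estimated correlation, 0.999 above index 8, 0.243 without DSS MHCII+ replicate 3). Their test pointed the other way above index 8. Fibroblast markers were called lower (camera adjusted p = 0.0208, adjusted p = 0.221 with an estimated correlation, 0.611 above index 8, 0.0653 with the block, lost at up to 0.0977 without DSS Ccr2+ replicate 1 or 4 or DSS MHCII+ replicate 3, 4 or 5), at summed 499 ± 156 against 1115 ± 375 CPM. Dendritic cell markers were called lower (camera adjusted p = 0.0382, adjusted p = 0.117 with an estimated correlation, 0.1002 without sort 5, lost at up to 0.0988 without DSS Ccr2+ replicate 2 or 3 or DSS MHCII+ replicate 2, 3 or 5), at summed 715 ± 98.8 against 991 ± 183 CPM. Over all genes 313 genes were called, 157 higher and 156 lower, against 197 called among libraries with an index above 8. 48 of the 58 called genes named by the rule and 13 of the 16 called lists kept the call whichever library was left out.

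**Figure D3:**
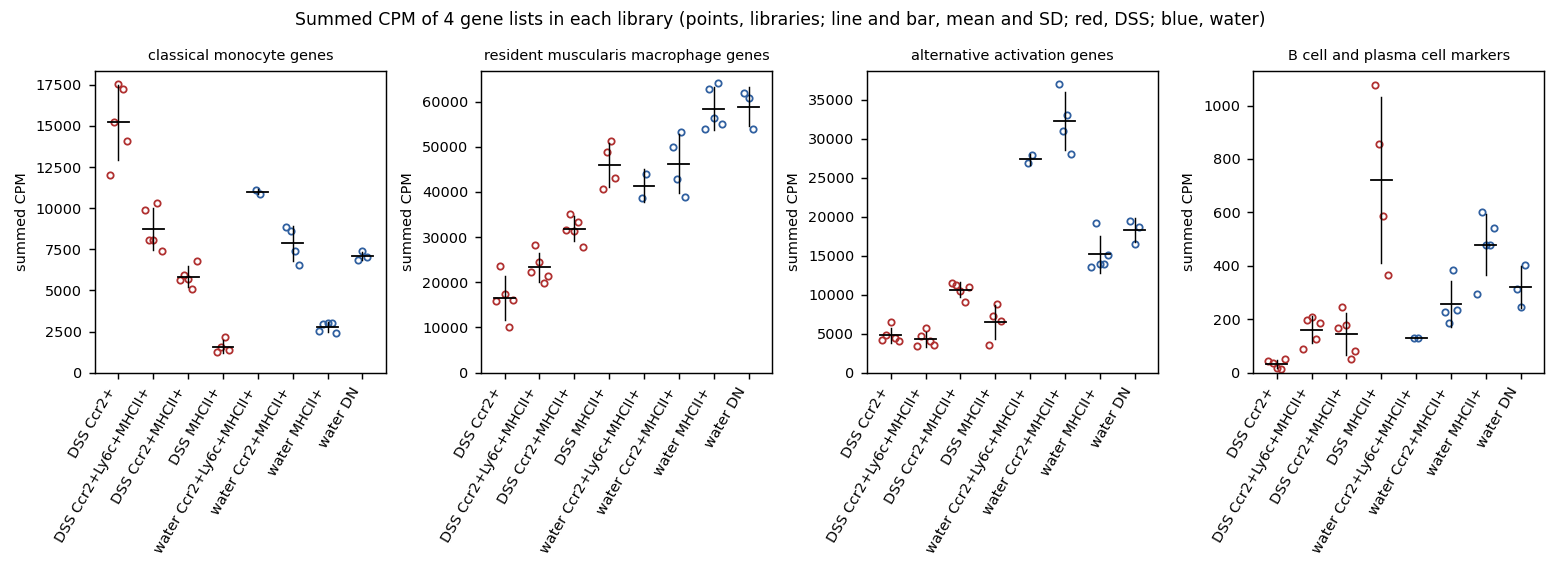
Summed CPM of the classical monocyte genes, resident muscularis macrophage genes, alternative activation genes and B cell and plasma cell markers in each library (red, DSS; blue, water), with each group's mean and SD. Monocyte genes summed to a mean of 15220.5 CPM in DSS Ccr2+ and 1582 in DSS MHCII+.

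Ccr2+Ly6c+MHCII+ cells were compared with Ccr2+ cells under DSS (5 libraries each). MHC class II genes were higher, among them H2-Ab1 (7749.5 ± 865 against 204 ± 108 CPM, log2 fold change 5.25 ± 0.30, adjusted p = 1.23e-11) and H2-Eb1 (log2 fold change 6.37 ± 0.42). The complement genes C1qa (2434 ± 939.6 against 959 ± 307 CPM, log2 fold change 1.34 ± 0.19, adjusted p = 2.86e-05) and C1qb (1593 ± 326 against 727 ± 308 CPM) were higher. Ighm (104 ± 32.1 against 16.98 ± 15.1 CPM) was higher in Ccr2+Ly6c+MHCII+. Retnla (1479.9 ± 768 against 44.4 ± 46.0 CPM, adjusted p = 0.0151, 0.0596 without DSS Ccr2+ replicate 5, 0.138 above index 8) was higher. MHC class II antigen presentation genes were higher (camera adjusted p = 3.00e-66), with 5 of 10 higher over all genes and 9 adjusted over the list alone. That direction was set by the MHCII gate. Classical monocyte genes were lower (camera adjusted p = 8.36e-04), with 0 of 16 lower over all genes and 2 adjusted over the list alone. Dissociation and immediate-early genes were higher (camera adjusted p = 2.38e-04, adjusted p = 0.0838 with an estimated correlation), with 0 of 18 higher over all genes and 0 adjusted over the list alone. Neutrophil markers were lower (camera adjusted p = 4.76e-04). B cell and plasma cell markers were higher (camera adjusted p = 3.71e-04), with 2 of 9 higher over all genes and 4 adjusted over the list alone. Fibroblast markers were called higher (camera adjusted p = 0.0288, adjusted p = 0.305 with an estimated correlation, lost at up to 0.190 without DSS Ccr2+ replicate 1 or 4 or DSS Ccr2+Ly6c+MHCII+ replicate 2, 3 or 4), at summed 821 ± 334 against 499 ± 156 CPM. Over all genes 23 genes were called, 21 higher and 2 lower, with 35 called without DSS Ccr2+ replicate 3. 9 of the 11 called genes named by the rule and 5 of the 7 called lists kept the call whichever library was left out.

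Between Ccr2+MHCII+ and Ccr2+Ly6c+MHCII+ cells under DSS (5 libraries each), Fcgrt (276 ± 56.2 against 80.0 ± 47.6 CPM, log2 fold change 1.79 ± 0.34, adjusted p = 0.00126), the neonatal Fc receptor gene, was higher in Ccr2+MHCII+. Pmepa1 (55.3 ± 24.9 against 4.07 ± 4.30 CPM, log2 fold change 3.74 ± 0.77, adjusted p = 0.00410), a regulator of TGF-beta signalling, was higher. Resident muscularis macrophage genes were higher (camera adjusted p = 6.93e-13), with 1 of 22 higher over all genes and 3 adjusted over the list alone. Alternative activation genes were higher (camera adjusted p = 4.27e-05), with 1 of 15 higher over all genes and 8 adjusted over the list alone. Chemokine and monocyte-recruitment genes were higher (camera adjusted p = 0.00111), with 0 of 22 higher over all genes and 3 adjusted over the list alone. Cell cycle genes were higher (camera adjusted p = 0.00111), with 0 of 19 higher over all genes and 3 adjusted over the list alone. Classical monocyte genes were lower (camera adjusted p = 3.37e-06), with 0 of 16 lower over all genes and 2 adjusted over the list alone. Genes of MHC class II antigen presentation were higher (camera adjusted p = 0.00111, adjusted p = 0.1002 with an estimated correlation), with 0 of 10 higher over all genes and 1 adjusted over the list alone. Efferocytosis and scavenger receptors were higher (camera adjusted p = 0.0131, adjusted p = 0.0561 with an estimated correlation, 0.0750 above index 8, 0.138 without sort 5, 0.0679 without DSS Ccr2+Ly6c+MHCII+ replicate 5), with 1 of 17 higher over all genes and 1 adjusted over the list alone. Dendritic cell markers were higher (camera adjusted p = 3.37e-06), with 0 of 15 higher over all genes and 3 adjusted over the list alone. Over all genes 13 genes were called, 12 higher and 1 lower. The number was 22 among libraries with an index above 8 and 8 with a term for the index. It was 26, 7 and 8 without Ccr2+Ly6c+MHCII+ replicate 2, 3 and 4, and 8 without Ccr2+MHCII+ replicate 5. 2 of the 4 called genes named by the rule and 7 of the 9 called lists kept the call whichever library was left out.

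MHCII+ cells were compared with Ccr2+MHCII+ cells in each treatment. Under DSS (4 against 5 libraries), MHCII+ cells had higher Ccl4 (973 ± 95.9 against 225 ± 76.0 CPM, log2 fold change 2.11 ± 0.33, adjusted p = 1.47e-06). Ccl3 (838 ± 168 against 227 ± 75.2 CPM) and Timp2 (732 ± 154 against 242 ± 36.5 CPM) were higher, as was Jun (log2 fold change 1.44 ± 0.19). MHCII+ cells had lower S100a4 (56.5 ± 46.0 against 848 ± 274 CPM, log2 fold change -3.91 ± 0.47, adjusted p = 9.95e-06). S100a6 (406 ± 151 against 2284 ± 431 CPM, log2 fold change -2.49 ± 0.19, adjusted p = 2.17e-32) was lower. Il1b (1004 ± 94.9 against 2846 ± 512 CPM), Lgals3 (300.5 ± 86.5 against 737 ± 170.4 CPM) and Mmp19 (43.0 ± 19.8 against 203 ± 94.7 CPM) were lower in MHCII+. Fn1 (35.7 ± 25.4 against 479 ± 117 CPM, adjusted p = 0.0121, 0.0521 without DSS MHCII+ replicate 4, 0.198 above index 8), the fibronectin gene, was lower too. Classical monocyte genes were lower (camera adjusted p = 8.87e-17), with 3 of 16 lower over all genes and 7 adjusted over the list alone. Resident muscularis macrophage genes were higher (camera adjusted p = 7.32e-09), with 1 of 22 higher over all genes and 8 adjusted over the list alone. Glycolysis and hypoxia genes were lower (camera adjusted p = 1.24e-04), with 0 of 16 lower over all genes and 1 adjusted over the list alone. Matrix and protease genes were lower (camera adjusted p = 0.0111, 0.0562 without sort 5), with 2 of 18 lower over all genes and 6 adjusted over the list alone. Genes of MHC class II antigen presentation were lower (camera adjusted p = 0.00334, adjusted p = 0.141 with an estimated correlation), with 0 of 10 lower over all genes and 0 adjusted over the list alone. B cell and plasma cell markers were higher (camera adjusted p = 2.76e-08, 0.0831 above index 8), with 0 of 9 higher over all genes and 5 adjusted over the list alone. Smooth muscle markers were higher (camera adjusted p = 0.00334), with 0 of 12 higher over all genes and 1 adjusted over the list alone. Enteric neuron markers were called higher (camera adjusted p = 0.00771, adjusted p = 0.134 with an estimated correlation, 0.863 above index 8, 0.291 without DSS MHCII+ replicate 3). Their test pointed the other way above index 8. Mitochondrial transcripts made up 10.1% ± 1.45 of counts in MHCII+ against 6.48% ± 1.20, and ribosomal protein genes 2.67% ± 0.862 against 3.45% ± 0.553. Over all genes 56 genes were called, 16 higher and 40 lower (22 and 35 with RLE size factors). 13 of the 22 called genes named by the rule and 7 of the 8 called lists kept the call whichever library was left out.

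In water, Ccr2+MHCII+ were compared with MHCII+ cells (4 against 5 libraries). Fn1 (883 ± 182 against 22.2 ± 8.11 CPM, log2 fold change 5.32 ± 0.73, adjusted p = 5.58e-05) was higher in Ccr2+MHCII+. S100a6 (4214 ± 627 against 1002 ± 244 CPM, log2 fold change 2.07 ± 0.18, adjusted p = 1.28e-25) and Lgals3 (1296 ± 310.1 against 359 ± 119.9 CPM) were higher. Ccr2 (log2 fold change 3.13 ± 0.65, adjusted p = 0.0111, 0.0661 above index 8) was higher. MHCII+ cells had higher Stab1 (148 ± 42.7 against 1197 ± 163 CPM, log2 fold change -3.02 ± 0.32, adjusted p = 1.21e-17), a scavenger receptor gene. They had higher Selenop (515 ± 232 against 2179 ± 468 CPM, log2 fold change -2.08 ± 0.22, adjusted p = 7.66e-16), which overlaps Ccdc152, and the transcription factor gene Maf (358 ± 141 against 1327 ± 57.5 CPM). Apoe (7156 ± 2351 against 21228 ± 2084 CPM), F13a1 (517 ± 139.7 against 1305 ± 324 CPM) and Ccl3 (231 ± 143 against 849 ± 161 CPM) were lower in Ccr2+MHCII+. Classical monocyte genes were higher (camera adjusted p = 1.76e-11), with 4 of 16 higher over all genes and 9 adjusted over the list alone. F13a1, a member of the same list, was lower. Genes of MHC class II antigen presentation were higher (camera adjusted p = 2.61e-08), with 1 of 10 higher over all genes and 4 adjusted over the list alone. Cell cycle genes were higher (camera adjusted p = 0.00660, 0.0664 above index 8), with 0 of 19 higher over all genes and 0 adjusted over the list alone. Resident muscularis macrophage genes were lower (camera adjusted p = 6.07e-20), with 6 of 22 lower over all genes and 15 adjusted over the list alone. Efferocytosis and scavenger receptors were lower (camera adjusted p = 0.00124), with 1 of 17 lower over all genes and 5 adjusted over the list alone. Dissociation and immediate-early genes were lower (camera adjusted p = 6.88e-09), with 3 of 18 lower over all genes and 10 adjusted over the list alone.

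Markers of other cells also differed between these water groups. Dendritic cell markers were higher (camera adjusted p = 3.48e-06), with 2 of 15 higher over all genes and 9 adjusted over the list alone. Fibroblast markers were lower (camera adjusted p = 4.20e-06), among them Col3a1 (log2 fold change -7.33 ± 1.53). Smooth muscle markers were lower (camera adjusted p = 7.82e-05), at summed 122 ± 46.8 against 577 ± 83.0 CPM. Enteric neuron markers were called lower (camera adjusted p = 0.0328, adjusted p = 0.183 with an estimated correlation, 0.148 above index 8, 0.141 without sort 5, 0.0656 with the block, lost at up to 0.0852 without water Ccr2+MHCII+ replicate 2 or 5 or water MHCII+ replicate 2 or 5), at summed 4.69 ± 5.46 against 48.2 ± 38.2 CPM. Mitochondrial transcripts made up 6.77% ± 0.885 of counts against 9.22% ± 1.31, and ribosomal protein genes 2.90% ± 0.387 against 2.17% ± 0.214. Over all genes 149 genes were called, 96 higher and 53 lower. 20 of the 37 called genes named by the rule and 9 of the 10 called lists kept the call whichever library was left out. Of the genes lower in MHCII+ than in Ccr2+MHCII+ under DSS, 23 were also lower in water, against 0.254 expected of independent lists. Of those higher in MHCII+ under DSS, 11 were also higher in water, against 0.0561 expected. The 2 treatments share sorting experiments.

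MHCII+ cells were compared with DN cells in water (5 against 3 libraries). MHC class II genes were higher, among them H2-Ab1 (8236 ± 1806 against 109.8 ± 22.3 CPM, log2 fold change 6.23 ± 0.39, adjusted p = 2.66e-11) and H2-DMb1 (447 ± 82.2 against 28.3 ± 14.4 CPM). MHCII+ cells had higher Il1b (355 ± 73.8 against 51.9 ± 34.5 CPM, log2 fold change 2.77 ± 0.26, adjusted p = 4.76e-13). Cx3cr1 (642 ± 109 against 125 ± 49.2 CPM) and Apoe (21228 ± 2084 against 7903 ± 1819 CPM) were higher. DN cells had higher Lgals3 (359 ± 119.9 against 1188 ± 296 CPM, log2 fold change -1.73 ± 0.26, adjusted p = 2.35e-08). S100a6 (1002 ± 244 against 3032 ± 325 CPM, log2 fold change -1.60 ± 0.18, adjusted p = 1.22e-13) and F13a1 (1305 ± 324 against 2806 ± 259.8 CPM) were higher in DN. Grn (1006 ± 264 against 2409 ± 543 CPM, log2 fold change -1.26 ± 0.25, adjusted p = 3.26e-04), which encodes the lysosomal and neurotrophic protein progranulin, was higher in DN. MHC class II antigen presentation genes were higher (camera adjusted p = 1.96e-75), with 7 of 10 higher over all genes and 8 adjusted over the list alone. These groups were sorted apart by MHCII, so that this direction was set by the gate. Enteric neuron markers were called higher (camera adjusted p = 0.0396, adjusted p = 0.451 with an estimated correlation, 0.0822 above index 8, 0.166 without sort 5, 0.131 with the block, lost at up to 0.137 without water DN replicate 2, 4 or 5 or water MHCII+ replicate 2 or 5), at summed 48.2 ± 38.2 against 5.92 ± 1.68 CPM. Genes detected numbered 9147 ± 656 in MHCII+ against 10080.3 ± 445 in DN. Over all genes 62 genes were called, 39 higher and 23 lower. 20 of the 27 called genes named by the rule and 1 of the 3 called lists kept the call whichever library was left out.

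Ccr2+Ly6c+MHCII+ and Ccr2+MHCII+ cells in water (2 pools against 4 libraries) differed in 3 called genes by edgeR, 3 higher and 0 lower. At an unadjusted p under 0.05 there were 1078. In the comparison named Ccr2+Ly6c+MHCII+ against Ccr2+MHCII+ in water, DESeq2 called 957 and limma-voom 389. Genes detected numbered 10779.5 ± 101 in the pools against 8553 ± 469.8. Cfb (55.7 ± 12.2 against 0 CPM, at least 275-fold, adjusted p = 6.08e-04) was called with Gm20547, which overlaps it. Dok3 (144 ± 73.7 against 17.1 ± 23.1 CPM, adjusted p = 0.0333) was higher. Its adjusted p was 0.0597 to 1.00 without any 1 of Ccr2+Ly6c+MHCII+ replicate 1, Ccr2+Ly6c+MHCII+ replicate 2, Ccr2+MHCII+ replicate 3, Ccr2+MHCII+ replicate 4 or Ccr2+MHCII+ replicate 5, and 0.0866 above index 8. Classical monocyte genes were higher (camera adjusted p = 0.00349, 0.267 without water Ccr2+Ly6c+MHCII+ replicate 1), with 0 of 16 higher over all genes and 3 adjusted over the list alone. Dendritic cell markers were lower (camera adjusted p = 4.28e-04, 0.180 without water Ccr2+Ly6c+MHCII+ replicate 2). Epithelial markers were higher (camera adjusted p = 1.43e-09, adjusted p = 0.224 with an estimated correlation), with 0 of 14 called over all genes, and both pools contain cells of sort 5. The number of called genes was 12 among libraries with an index above 8, 7 without sort 5 and 7 without Ccr2+Ly6c+MHCII+ replicate 2. It was 8, 10, 12 and 6 without Ccr2+MHCII+ replicate 2, 3, 4 and 5. RLE size factors moved the median of all genes by -0.103 (log2). 1 of the 2 called genes named by the rule and 1 of the 3 called lists kept the call whichever library was left out.

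The difference of the DSS effect between Ccr2+MHCII+ and MHCII+ cells was tested as an interaction over these 4 groups of 5, 4, 4 and 5 libraries. Cd93 had 717 and 306 CPM in Ccr2+MHCII+ under DSS and water and 331 and 699 in MHCII+ (difference 2.31 ± 0.41, adjusted p = 2.21e-04). It encodes a receptor of phagocytes. Csf2ra had 868 and 1457 CPM in Ccr2+MHCII+ under DSS and water and 851 and 487 in MHCII+ (difference -1.55 ± 0.33, adjusted p = 0.00519), the receptor of GM-CSF. Zcchc9 had 123 and 4.93 CPM in Ccr2+MHCII+ under DSS and water and 31.3 and 94.2 in MHCII+ (difference 6.22 ± 1.23, adjusted p = 0.00150). Positive differences of log2 fold changes were also found for Tgfbi (1.97 ± 0.41, adjusted p = 0.0176, 0.154 without DSS MHCII+ replicate 3) and Stab1 (1.85 ± 0.41, adjusted p = 0.0111, 0.0550 without DSS MHCII+ replicate 2). The complement genes Cfb (10.81 ± 2.14, adjusted p = 0.00150, 0.0740 above index 8) and C3 (-8.95 ± 1.63, adjusted p = 4.69e-04) each had a group with no count, so that these are fitted values and no measure of size. Dissociation and immediate-early genes were higher (camera adjusted p = 3.17e-05, adjusted p = 0.0948 with an estimated correlation), with 0 of 18 higher over all genes and 3 adjusted over the list alone. Resident muscularis macrophage genes were higher (camera adjusted p = 4.45e-04, adjusted p = 0.278 with an estimated correlation), with 1 of 22 higher over all genes and 2 adjusted over the list alone. Higher here means a more positive DSS effect in Ccr2+MHCII+. B cell and plasma cell markers had a more negative one (camera adjusted p = 4.40e-04, adjusted p = 0.0948 with an estimated correlation, 0.594 above index 8). Over all genes 11 were called, 8 positive and 3 negative (5 and 3 with RLE size factors). 6 of the 9 called genes named by the rule and 3 of the 7 called lists kept the call whichever library was left out. The number was 19 among libraries with an index above 8 and 17 without DSS Ccr2+MHCII+ replicate 2. It was 18 and 17 without DSS MHCII+ replicate 4 and 5, and 22 and 23 without water Ccr2+MHCII+ replicate 2 and 4. Without water MHCII+ replicate 1, 2 and 5 it was 21, 17 and 20.

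Several lists were called in none of the 11 comparisons. The lowest camera adjusted p was 0.437 for secreted neurotrophic and neuron-supporting factors, 0.0803 for axon guidance ligands and 0.0654 for lipid-associated macrophage genes. It was 0.364 for T cell and innate lymphocyte markers, 0.572 for endothelial markers and 0.610 for enteric glia markers. Secreted neurotrophic and neuron-supporting factors summed to 3213 ± 654 CPM in water DN and 2035 ± 454 in water MHCII+. The mast cell and eosinophil markers, not tested as a list, summed to 14.5 ± 27.3 CPM in DSS Ccr2+MHCII+.

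**Figure D4:**
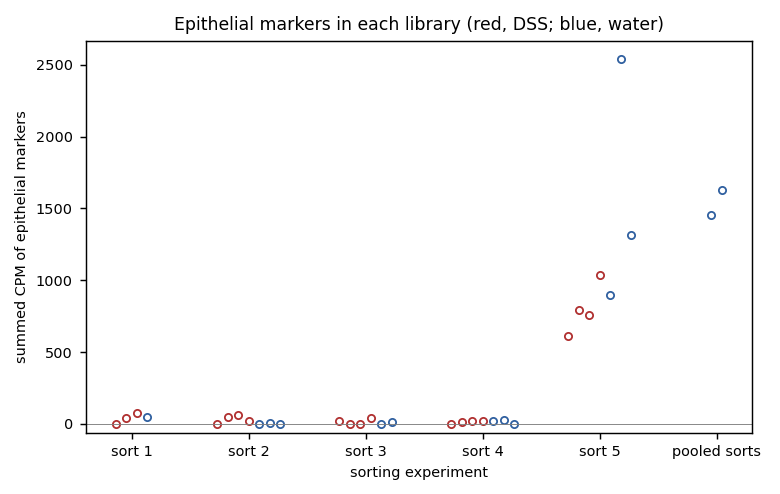
Summed CPM of the 14 epithelial markers in each library by sorting experiment (red, DSS; blue, water), with the 2 pooled libraries apart. The 7 libraries of sort 5 lie above every library of the other 4 sorts.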

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

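The tests of explanations, the counts over other splits of the libraries, and the fits by column index and without sort 5 were chosen after the results had been seen, whereas the tests of the difference between DSS effects were planned.

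The 6 groups of 4 or 5 libraries were examined for 38 measures each, and in 34 of these 228 cases 1 library lay far from the rest. Chance alone marks about 1 in 20, which is 11.4 here. DSS Ccr2+Ly6c+MHCII+ replicate 1 had the highest depth, with 6373040 (others 3678130 to 4271630) counts. Ly6c2 stood out at 13.3 (others at 0) CPM in DSS Ccr2+MHCII+ replicate 4, 2.42 (others at 0) in DSS MHCII+ replicate 4, 32.6 (others 0 to 1.65) in water Ccr2+MHCII+ replicate 5 and 0.559 (others at 0) in water MHCII+ replicate 5. Ly6c1 stood out at 24.5 (others at 0) CPM in DSS Ccr2+ replicate 3, 2.94 (others at 0) in DSS Ccr2+Ly6c+MHCII+ replicate 2, 18.6 (others at 0) in DSS MHCII+ replicate 3 and 0.762 (others at 0) in water Ccr2+MHCII+ replicate 3. H2-Ab1 had 12955 (others 14630.5 to 14809) CPM in water Ccr2+MHCII+ replicate 4.

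The other such libraries were found by the summed CPM of a list. Inflammatory genes summed to 16632 (others 18123 to 18278) in DSS MHCII+ replicate 2. Interferon-stimulated genes reached 2834 (others 946 to 1408) in DSS Ccr2+Ly6c+MHCII+ replicate 5. Alternative activation genes had 19197 (others 13602 to 15122) in water MHCII+ replicate 2. Dissociation and immediate-early genes were at 15813 (others 17311 to 17887) in DSS Ccr2+Ly6c+MHCII+ replicate 4 and 14568 (others 17542 to 18599) in DSS Ccr2+MHCII+ replicate 5. Neutrophil markers summed to 1636 (others 534 to 843) in DSS Ccr2+ replicate 4. T cell markers had 177 (others 23.2 to 28.4) in DSS Ccr2+Ly6c+MHCII+ replicate 5 and 124 (others 43.9 to 66.5) in DSS Ccr2+MHCII+ replicate 3. Mast cell and eosinophil markers had 15.0 (others at 0), 62.7 (others 0 to 10.0) and 29.8 (others 0 to 2.53) in DSS Ccr2+Ly6c+MHCII+ replicate 4, DSS Ccr2+MHCII+ replicate 5 and DSS MHCII+ replicate 3. Smooth muscle markers had 109 (others 19.9 to 37.4) in DSS Ccr2+ replicate 1 and 333 (others 12.9 to 42.7) in DSS Ccr2+Ly6c+MHCII+ replicate 1. Endothelial markers had 6.08 (others 72.6 to 94.6) in DSS Ccr2+Ly6c+MHCII+ replicate 5. Enteric glia markers had 116 (others 4.68 to 20.7) in DSS Ccr2+Ly6c+MHCII+ replicate 4 and 154 (others 0 to 34.4) in DSS Ccr2+MHCII+ replicate 5. Enteric neuron markers had 11.7 (others 0 to 0.260) and 45.3 (others 0 to 8.86) in replicate 3 of DSS Ccr2+ and of DSS Ccr2+Ly6c+MHCII+.

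Epithelial markers set replicate 5 apart in all 6 groups of 4 or 5 libraries, where they summed to 610.5 (others 0 to 17.7), 789 (others 0 to 49.4), 757 (others 2.28 to 75.7) and 1038 (others 19.4 to 41.1) CPM in the DSS groups Ccr2+, Ccr2+Ly6c+MHCII+, Ccr2+MHCII+ and MHCII+, and to 898 (others 0 to 22.9) and 1313 (others 0 to 51.3) in water Ccr2+MHCII+ and MHCII+. DSS treatment is argued against, since the highest DSS library outside sort 5 had 75.7 CPM and the lowest water library of sort 5 898. All 7 libraries of sort 5 lay above the 24 single-sort libraries of other sorts, and the 2 pools that hold part of sort 5 had 1451 and 1629, which is consistent with RNA or cells of the epithelium entering during that sort. Muc2 and Lgals4 had the highest means, at 333 and 229 CPM in sort 5 against 6.25 and 0.720 in other sorts, and a sort for macrophages would remove whole epithelial cells, which no test here told from free RNA; profiles of the 14 markers correlated across genes with a median r of 0.599 in 36 pairs of these libraries (lowest 0.117).

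Ahnak, Anxa2, Lgals1, S100a6, S100a10 and Tagln2 fell under DSS in all 3 subsets compared, which share sorting experiments. Of these, Ahnak kept its 3 calls whichever library was left out, and the libraries that decided the other calls are given with the DSS effects. A library batch by column index is argued against, since 17 of 18 calls were kept above index 8 and the median log2 change was -1.22 against -1.26; the lost call, S100a10 in MHCII+, went to an adjusted p of 0.0516. Epithelial RNA of sort 5 is argued against as the whole cause in MHCII+ and Ccr2+MHCII+, where 10 of 12 calls were kept without sort 5; in Ccr2+MHCII+, Ahnak went from -1.03 ± 0.22 to -0.91 ± 0.25 (adjusted p = 0.0587) and Lgals1 from -0.87 ± 0.21 to -0.85 ± 0.24 (adjusted p = 0.115), with changes that moved by less than their errors, and errors that grew with fewer libraries. In Ccr2+Ly6c+MHCII+, whose water pools hold sort 5, it could not be tested, and an effect of DSS on the cells, or on which cells entered the gates, stays open as a hypothesis.

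Of the 20 genes higher under DSS in MHCII+, 15 were also higher in Ccr2+MHCII+ than in MHCII+ in water, among them Il1r2, Fpr1 and Il1b (in water, 0.0547 without water Ccr2+MHCII+ replicate 4, 0.147 above index 8), against 0.127 expected of independent lists. These comparisons share the 5 water MHCII+ libraries, whose low values by chance are argued against as the whole cause: with these libraries divided between the comparisons in 10 ways, 5 to 8 genes were shared (median 7, at most 0.101 expected), while 5 simulations of unchanged groups shared 0 but called at most 1 gene in a list, too few to show an overlap. Ccr2+MHCII+ cells inside the MHCII+ gate under DSS cannot be told apart from a change in the cells. Each of 8 monocyte genes of at least 100 CPM, lower on average in MHCII+ than Ccr2+MHCII+, bounds the share of such cells (median 16.5%). The 3 called have upper 95% limits of 12.7 (S100a4), 20.2 (Fn1) and 22.9 (S100a6). Genes chosen as higher without 1 library of each group need a median of 16.7% in the libraries left out (quartiles -2.66 and 30.9). Il1b needs 26.0%, and the median limit of the 8 is 34.5%. Fpr1 and Serpina3n had 38.5 and 79.4 CPM in DSS MHCII+ against 18.5 and 30.3 in DSS Ccr2+MHCII+, differences not called. Either may contribute.

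The DSS effect differed between Ccr2+MHCII+ and MHCII+ cells, by the interaction term, in 11 genes. Differences of log2 fold changes (Ccr2+MHCII+ minus MHCII+) were positive for Cd93 (2.31 ± 0.41, adjusted p = 2.21e-04), Zcchc9 (6.22 ± 1.23, adjusted p = 0.00150), Tgfbi (1.97 ± 0.41, adjusted p = 0.0176, 0.154 without DSS MHCII+ replicate 3), Stab1 (1.85 ± 0.41, adjusted p = 0.0111, 0.0550 without DSS MHCII+ replicate 2) and Selenop (1.36 ± 0.30, adjusted p = 0.0130, 0.167 without water Ccr2+MHCII+ replicate 5 and 0.0652 without water MHCII+ replicate 4, 0.0723 above index 8, 0.0604 with the block). Reads of Selenop could not be told from those of Ccdc152 (1.36 ± 0.31, adjusted p = 0.0180). The difference was negative for Csf2ra (-1.55 ± 0.33, adjusted p = 0.00519). Cfb (10.81 ± 2.14, adjusted p = 0.00150, 0.0740 above index 8), its overlapping gene Gm20547 (10.74 ± 2.30, adjusted p = 0.00655), Tmsb10 (-9.31 ± 1.76, adjusted p = 6.68e-04, 0.212 above index 8) and C3 (-8.95 ± 1.63, adjusted p = 4.69e-04) each had a group at 0, so that their differences are fitted values of no fixed size. The calls of Ccdc152 and Gm20547 were not followed through the alternatives. Among lists, the DSS effect was more positive in Ccr2+MHCII+ for resident muscularis macrophage genes (camera adjusted p = 4.45e-04, adjusted p = 0.278 with an estimated correlation) and for dissociation and immediate-early genes (camera adjusted p = 3.17e-05, adjusted p = 0.0948 with an estimated correlation). It was also more positive for efferocytosis and scavenger receptors (camera adjusted p = 0.0382, adjusted p = 0.172 with an estimated correlation, 0.0986 above index 8, 0.268 without sort 5, 0.125 with the block, lost at up to 0.0918 without DSS Ccr2+MHCII+ replicate 1 or 2 or DSS MHCII+ replicate 2 or 5 or water Ccr2+MHCII+ replicate 3 or 5 or water MHCII+ replicate 4 or 5) and fibroblast markers (camera adjusted p = 0.00693, adjusted p = 0.273 with an estimated correlation, lost at up to 0.0799 without DSS MHCII+ replicate 2 or water Ccr2+MHCII+ replicate 2). The effect was more negative for MHC class II antigen presentation genes (camera adjusted p = 0.0382, adjusted p = 0.302 with an estimated correlation, 0.168 above index 8, lost at up to 0.202 without DSS Ccr2+MHCII+ replicate 2, 3 or 4 or DSS MHCII+ replicate 2, 3 or 5 or water Ccr2+MHCII+ replicate 2, 3 or 5 or water MHCII+ replicate 3), dendritic cell markers (camera adjusted p = 0.0176, adjusted p = 0.172 with an estimated correlation, lost at up to 0.0622 without DSS Ccr2+MHCII+ replicate 4 or DSS MHCII+ replicate 2 or 5 or water Ccr2+MHCII+ replicate 3 or water MHCII+ replicate 4) and B cell and plasma cell markers (camera adjusted p = 4.40e-04, adjusted p = 0.0948 with an estimated correlation, 0.594 above index 8).

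Other splits of the libraries into groups of the same sizes were counted by called genes, with 50 splits drawn per comparison, the real one included, or all 56 for MHCII+ against DN. These were drawn without regard to sort. Among them, as many genes as in the real split were called in 1 split, the real one itself, in each of the 8 comparisons without a pool. Outside DN most splits were not run, so chance is not excluded: for Ccr2+Ly6c+MHCII+ against Ccr2+ an undrawn one called more. The real and highest other counts were 33 against at most 26 for the DSS effect in MHCII+, 52 against at most 13 for that in Ccr2+MHCII+ and 313 against at most 134 for Ccr2+ against MHCII+ in DSS. They were 23 against at most 14 for Ccr2+Ly6c+MHCII+ against Ccr2+, 13 against at most 3 for Ccr2+MHCII+ against Ccr2+Ly6c+MHCII+ and 56 against at most 13 for MHCII+ against Ccr2+MHCII+, all in DSS. In water they were 62 against at most 16 for MHCII+ against DN and 149 against at most 16 for Ccr2+MHCII+ against MHCII+. Splits that part as many same-sort pairs as the real one were too few for a share under 0.05, with 15 others per comparison and 7 for DN. Their highest counts, in the order above, were 15, 13, 133, 32, 3, 11, 10 and 49. The 32 exceeded the real 23 and came from DSS Ccr2+Ly6c+MHCII+ replicate 1, 2 and 5 with DSS Ccr2+ replicate 3 and 4 against the rest, while the blocked fit of the real split called 22. For the difference of the DSS effect, 2 of 50 splits called as many as the real 11, the real one included. These splits did not keep the sorts together, and chance is not excluded there either. The other called 76, which points to a structure of the samples. Its first group was DSS Ccr2+MHCII+ replicate 1, 2, 4 and 5, DSS MHCII+ replicate 2 and water MHCII+ replicate 1, 2, 3 and 4, so that it mostly set the 2 subsets apart, in opposite order under DSS and in water.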

How the results depend on the processing

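The fits by column index and without sort 5, camera in them and with libraries left out, and the splits under DESeq2 were chosen after the results had been seen. In the order DSS effect in MHCII+, DSS effect in Ccr2+MHCII+, DSS effect in Ccr2+Ly6c+MHCII+, Ccr2+ against MHCII+ in DSS, Ccr2+Ly6c+MHCII+ against Ccr2+ in DSS, Ccr2+MHCII+ against Ccr2+Ly6c+MHCII+ in DSS, MHCII+ against Ccr2+MHCII+ in DSS, MHCII+ against DN in water, Ccr2+MHCII+ against MHCII+ in water, Ccr2+Ly6c+MHCII+ against Ccr2+MHCII+ in water and difference of the DSS effect, Ccr2+MHCII+ minus MHCII+, edgeR called 33, 52, 29, 313, 23, 13, 56, 62, 149, 3 and 11 genes. In that order DESeq2 called 816, 1139, 977, 1507, 928, 903, 961, 938, 1342, 957 and 1000. In 10 other splits of the libraries of the first comparison DESeq2 called 694 to 867 (median 804.5), so that its count there did not separate the real groups from others. In the same order limma-voom called 55, 174, 591, 729, 68, 60, 227, 247, 381, 389 and 16. Given here are counts that moved by over 1.5 times. RLE size factors kept all 11 counts within 1.5 times, and so did omitting the filter in 10, with 10 for Ccr2+Ly6c+MHCII+ against Ccr2+MHCII+ in water. Fits of the compared groups alone gave 15 for DSS effect in MHCII+, 75 for DSS effect in Ccr2+Ly6c+MHCII+, 10 for Ccr2+Ly6c+MHCII+ against Ccr2+ in DSS, 1 for Ccr2+Ly6c+MHCII+ against Ccr2+MHCII+ in water and 3 for difference of the DSS effect, Ccr2+MHCII+ minus MHCII+. Libraries with an index above 8 gave 53 for DSS effect in MHCII+, 64 for DSS effect in Ccr2+Ly6c+MHCII+, 197 for Ccr2+ against MHCII+ in DSS, 22 for Ccr2+MHCII+ against Ccr2+Ly6c+MHCII+ in DSS, 12 for Ccr2+Ly6c+MHCII+ against Ccr2+MHCII+ in water and 19 for difference of the DSS effect, Ccr2+MHCII+ minus MHCII+. A term for the index gave 8 for Ccr2+MHCII+ against Ccr2+Ly6c+MHCII+ in DSS and 7 for Ccr2+Ly6c+MHCII+ against Ccr2+MHCII+ in water. Without sort 5 the numbers were 44 for DSS effect in Ccr2+Ly6c+MHCII+ and 7 for Ccr2+Ly6c+MHCII+ against Ccr2+MHCII+ in water. The cause of these moves was not tested, though fewer libraries entered the fits above index 8, without sort 5 and of the compared groups. Leaving out each library in turn gave, in the order above, 27 to 48, 41 to 62, 12 to 47, 233 to 326, 21 to 35, 7 to 26, 39 to 80, 67 to 73, 124 to 169, 2 to 12 and 11 to 23, and 83 of these counts lay within 1.5 times of the reported ones, with the libraries behind the others named at each comparison. With a group left at 1 library, that library was assumed to vary like those of other groups. With the sorting experiment as a block, the 9 comparisons without pools had 29, 58, 306, 22, 12, 68, 57, 150 and 11, all within 1.5 times. The block ended 25 and added 4 calls among named genes, and ended 4 and added 2 among lists, and changed no other call of a named gene or list, which are the calls that were followed. No paired analysis was possible because the pools mix sorts in DSS effect in Ccr2+Ly6c+MHCII+ and in Ccr2+Ly6c+MHCII+ against Ccr2+MHCII+ in water. Among lists, 3 calls ended with the direction turned above index 8: B cell and plasma cell markers in DSS effect in MHCII+ (0.789) and enteric neuron markers in Ccr2+ against MHCII+ in DSS (0.999) and in MHCII+ against Ccr2+MHCII+ in DSS (0.863), as adjusted p. Of the 78 list calls, 52 were kept whichever library was left out, and an estimated correlation ended 33. Above index 8, 14 further list calls ended without turning direction, and 3 were added. List calls ended and added numbered 13 and 2 without sort 5, 1 and 3 with RLE and 7 and 8 with voom weights, and the index term ended 3. Named-gene calls ended and added numbered 17 and 2 with RLE, 5 and 15 without the filter, 2 and 175 with DESeq2, 40 and 77 with limma-voom, and 60 and 20 in fits of the compared groups. They numbered 65 and 11 above index 8, 25 and 7 with the index term, and 55 and 14 without sort 5. No named gene turned direction past the threshold. Leaving out libraries under 1000000 counts removed none and tests nothing. Small changes could seldom be called: at a mean CPM of at least 20 no simulated 2-fold change was, and genes without a call may still differ.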

Other observations

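The overlaps below, the divisions of shared libraries and the choice of Retnla came after the results had been seen, whereas the list tests were planned. Alternative activation genes, a programme of macrophages in type 2 immunity, summed to 32286 ± 3780.3 CPM in water Ccr2+MHCII+, 27388 ± 683 in water Ccr2+Ly6c+MHCII+, 18254 ± 1549 in DN and 15157 ± 2332 in water MHCII+. Under DSS the sums were 10653 ± 956 in Ccr2+MHCII+, 6518 ± 2212 in MHCII+, 4771 ± 975 in Ccr2+ and 4266 ± 976 in Ccr2+Ly6c+MHCII+. The list test gives each gene equal weight, and alternative activation genes were called lower under DSS in Ccr2+Ly6c+MHCII+ (camera adjusted p = 0.0230, adjusted p = 0.230 with an estimated correlation, 0.0721 without sort 5, lost at up to 0.353 without water Ccr2+Ly6c+MHCII+ replicate 1 or 2) and were not called in Ccr2+MHCII+ (camera adjusted p = 0.811). Retnla, encoding secreted RELM-alpha, was most of the sum in water Ccr2+MHCII+ (26774 CPM) and Ccr2+Ly6c+MHCII+ (23580.5). It had 7429 in water MHCII+. In MHCII+ its libraries lay at 231 to 2213 CPM under DSS and 5251 to 10349.6 in water (adjusted p = 0.377). Those of Ccr2+MHCII+ lay at 5623 to 7414 CPM under DSS and 22746 to 30760.1 in water (adjusted p = 0.347), and those of Ccr2+Ly6c+MHCII+ at 748 to 2509.8 CPM under DSS and 22652 to 24509 in water (adjusted p = 0.165). The DSS and water libraries thus did not overlap in any of the 3 subsets. No difference was called, and the reason was not tested.

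Chil3, another gene of that programme, had 2172 ± 1006 against 6.97 ± 13.5 CPM in Ccr2+ against MHCII+ cells under DSS (adjusted p = 0.0172, 0.0549 without DSS MHCII+ replicate 4), and 2.56 ± 3.89 against 444 ± 287 CPM in Ccr2+MHCII+ against Ccr2+Ly6c+MHCII+ (adjusted p = 0.134). Lipid-associated macrophage genes summed to 25644 ± 2416 CPM in DSS and 26086 ± 2235 in water MHCII+, against means of 12661 to 16285 in other groups. Apoe can be most of the sum, and the list was never called. Cell cycle genes summed to 632 ± 196 CPM in water Ccr2+MHCII+ and 368 ± 103 under DSS, and the DSS effect was not called (camera adjusted p = 0.437).

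Of the 39 genes higher under DSS in Ccr2+MHCII+, 11 were lower in Ccr2+MHCII+ than in MHCII+ in water, among them Cd93, Stab1, Cxcl16, Col3a1 and Dok3, against 0.137 expected of independent lists. The comparisons share the 4 water Ccr2+MHCII+ libraries. With these divided in 6 ways, 0 to 4 genes were shared (median 1.5, at most 0.113 expected), while 5 simulations of unchanged groups shared 0 but called at most 1 gene in a list, too few to show an overlap. The divided comparison called 11 to 50 genes, and the shared libraries are not excluded as a source of part of the excess. Between the treatments, 1 gene, Cd93, was lower in MHCII+ than in Ccr2+MHCII+ under DSS and higher in water. Independent lists give 0.140, leaving out shared sorting experiments.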
